A study of Homo sapiens with 15 samples.

How the data were processed

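The data are RNA sequencing of Molm-13 cells in 15 libraries, 3 per group. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads, fragmented and copied with random primers, and libraries were amplified by PCR and sequenced on an Illumina instrument. The submitters' processing notes name fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR, with no role or order. The genome build, the annotation, the counting tool and whether the counting used strand are not given in the sources used here, so no coordinates are printed, and reads of a gene and of an antisense or overlapping partner cannot be told apart. A protocol that marks strand is not described in the labels.

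The deposited table holds estimated counts per gene for each library, as deposited by the authors, of which 9.63% to 11.3% per library were not whole numbers (tolerance 0.01), and the authors' TPM values in further columns. The TPM columns each sum to 1000000, keep no depth, and were used only to check levels. Estimated counts were rounded to whole numbers before testing. The table has 20375 genes by Ensembl gene identifier and symbol, 20322 of them in the reference table of gene names, of which 16471 had a count in any library. A gene symbol was missing for 645 genes, which were tested but not named, and 27 symbols stood on more than 1 line. Total counts ran from 10.9 to 16.97 M per library, and a group without counts was given a floor of 3 counts over its libraries. Intervals and floors given for single genes cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

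Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes passed filterByExpr on the groups (minimum count 10, minimum total 15), which left 12356, library sizes were scaled by TMM, and 1 quasi-likelihood fit over all 5 groups, with 10 residual degrees of freedom and a common biological coefficient of variation of 0.0433, gave every contrast. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use TMM-scaled library sizes. The contrasts were each cytarabine dose against control, FL-Fc-DM1 against cytarabine at each dose, the higher against the lower cytarabine dose, the difference of the FL-Fc-DM1 change between doses, each FL-Fc-DM1 group against control, and the mean FL-Fc-DM1 change over both doses. Changes are relative to the total count of a library. A total change of RNA per cell cannot be seen in them.

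Gene lists were tested with limma's camera, with a correlation preset at 0.01, on log2 CPM with voom weights, and with Benjamini-Hochberg adjustment over the 25 of 28 lists with at least 3 testable genes. The lists cover p53 targets, DNA replication, mitosis, homologous recombination and Fanconi repair, replication-dependent histones, tubulins, NF-kappaB and inflammatory cytokines, interferon-stimulated genes, monocyte and macrophage differentiation, the granulocyte programme, stem cell and KMT2A-fusion targets, STAT5 targets, MAPK feedback, MYC targets and ribosome biogenesis, the BCL2 family, the ATF4 stress response, the unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, the lysosome, cytarabine transport and metabolism, mitochondrially encoded genes, and markers of T and NK cells, B cells, erythroid cells, megakaryocytes, and stroma and epithelium. Some genes stand in more than 1 list. Every list that passed had a median and a mean of the sign of its test.

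The groups, lists, tests, alternatives and naming rule were fixed before the data were examined, with list tests for cytarabine against control and FL-Fc-DM1 against cytarabine at each dose. The list tests in the 5 other comparisons were added once the data were in hand. The rule named FLT3 in every comparison. For cytarabine against control and FL-Fc-DM1 against cytarabine it named the 6 largest rises and 6 largest falls among called genes with a symbol, at least 10 CPM in a group and no overlap between the 3 values of each group. It also named the 3 members of smallest p in the direction of each list that passed camera, and up to 2 members of each other list. In the other comparisons it named the 3 largest rises and falls by the same criteria, without the one on overlap for the difference between doses. Some genes that the rule selected are not reported here. A gene selected in a comparison may also be named, with its values, in another.

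Alternatives were DESeq2 size factors in the same edgeR fit, no low-count filter, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out in turn, a log2 threshold of 1, camera with an estimated correlation, and fry. A limma voom fit with a spread per group was added after seeing the data, because replicates of the 1 µM groups spread more. The test was checked on data simulated for FL-Fc-DM1 against cytarabine at 0.5 µM, with 12356 genes, 200 of them changed by known amounts, 30 others shifted as a list and 12126 unchanged. Of all of these 12177 passed the filter. Correlations between comparisons that share libraries were set beside 20 simulations of unchanged groups. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.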

Results

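Poly(A) RNA from Molm-13 cells was sequenced in 15 libraries, 3 in each of 5 groups. Molm-13 is a human monocytic acute myeloid leukemia line that carries an internal tandem duplication in FLT3, the gene of a receptor tyrosine kinase that drives growth of early blood cells. Control cells were grown for 4 days without drug. Cytarabine, a nucleoside analog that blocks DNA synthesis, was given at 0.5 or 1 µM for all 4 days. The remaining groups received cytarabine at 0.5 or 1 µM for 3 days, after which it was withdrawn and FL-Fc-DM1 was given at 1 nM for 24 hours. The labels do not spell out FL-Fc-DM1. DM1 is the usual name of mertansine, a maytansinoid that binds tubulin, and FL is a common short form of FLT3 ligand. The title of the series asks how FL-Fc-DM1 changes expression in cells pretreated with cytarabine. Because cytarabine was withdrawn when FL-Fc-DM1 was added, a difference between an FL-Fc-DM1 group and its cytarabine group holds both changes. The treatment protocol in the labels names THP-1 cells, another monocytic leukemia line, for the FL-Fc-DM1 groups, whereas the sample titles, the cell line entries and the series design name Molm-13.

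Total counts, with M for mega, ranged from 10.9 to 16.97 M per library. The group means were 15.7 M in control, 13.2 M at cytarabine 0.5 µM, 13.6 M at 1 µM, and 12.9 and 11.0 M after FL-Fc-DM1 at the lower and higher pretreatment dose. Mitochondrially encoded genes took 4.64 ± 0.128% of counts in control (SD, n = 3), 6.62 ± 0.160% and 6.68 ± 0.0393% after cytarabine, and 6.40 ± 0.0636% and 6.30 ± 0.0698% after FL-Fc-DM1. The 82 ribosomal protein genes took 10.4 ± 0.303% of counts in control, 9.46 ± 0.239% and 9.41 ± 0.117% after cytarabine, and 8.47 ± 0.166% and 8.02 ± 0.353% after FL-Fc-DM1. The first principal component of log2 CPM held 60.7% of the variance and set the control libraries apart from the other groups. The second, with 12.9%, separated the FL-Fc-DM1 groups from the cytarabine groups, and the third, with 6.81%, separated the doses. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. Levels are mean CPM ± SD (n = 3 per group) and log2 fold changes are given ± SE. FL-Fc-DM1 was always at 1 nM, and a dose in µM beside it is the cytarabine pretreatment dose.

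**Figure D1:**
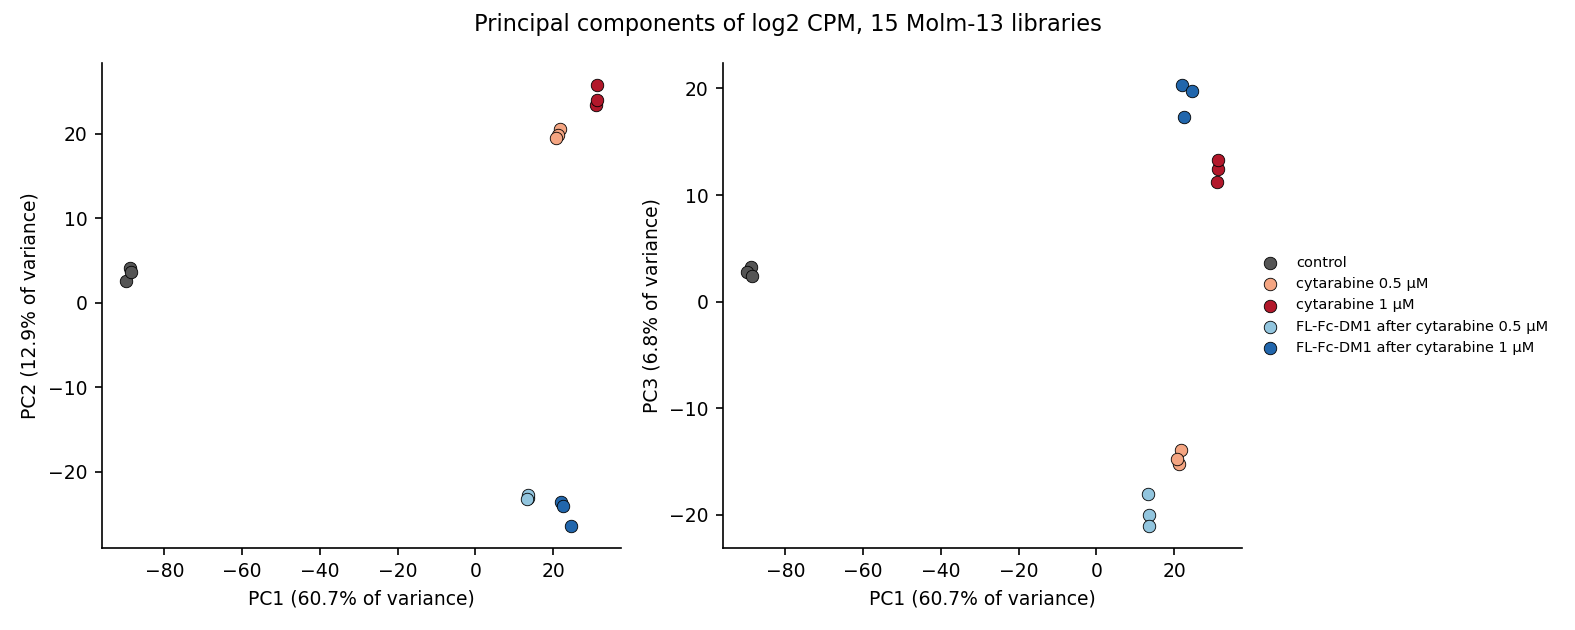
Principal component scores of the 15 libraries from log2 CPM, with the first component on both horizontal axes and a further component on each vertical axis; each point is a library, coloured by group. The first component (60.7% of the variance) parts control from all treated groups, and the second (12.9%) parts FL-Fc-DM1 from cytarabine.

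Monocyte and macrophage genes rose after 4 days of cytarabine at 0.5 µM, and genes of DNA replication, mitosis and the ATF4 stress response fell. LYZ, which encodes the antibacterial enzyme lysozyme, rose 22.8-fold, from 379 ± 12.4 CPM in control to 8624 ± 273 CPM. S100A9, a calcium-binding protein of myeloid cells, rose from 0.5101 ± 0.103 to 44.8 ± 3.84 CPM. MKI67, the gene of the proliferation marker Ki-67, fell from 381 ± 12.03 to 70.1 ± 4.19 CPM, and PSAT1, an enzyme of serine synthesis, fell from 590.0 ± 12.2 to 41.1 ± 2.81 CPM. FLT3 mRNA (ENSG00000122025) rose 1.48-fold, from 395 ± 8.51 to 587 ± 9.62 CPM, a log2 fold change of 0.57 ± 0.032. In edgeR's quasi-likelihood test, 9047 of 12356 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 4697 rose, 4350 fell and 2646 differed at least 2-fold.

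The largest rises at 0.5 µM that the naming rule admits were in CYP27A1, a sterol hydroxylase (1.47 ± 0.322 to 177 ± 6.104 CPM), in ADAMDEC1, a metalloprotease of macrophages (116-fold), and in APOE, a lipid carrier (92.8-fold). S100A9, the membrane protein gene TMEM176B and the orphan receptor gene GPR82 followed, with 86.4-, 80.6- and 68.4-fold rises. The largest falls it admits were in STC2, a secreted glycoprotein induced by stress (87.3 ± 0.8301 to 0.733 ± 0.0932 CPM), SLC6A9, a glycine transporter (105-fold), CHAC1, a glutathione-degrading enzyme (93.6-fold), INHBE, SHISA2 and PPM1E. Among these 12 genes the highest adjusted p was 2.31e-13, for INHBE (edgeR quasi-likelihood test, Benjamini-Hochberg).

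Among the gene lists fixed before the data were examined, 24 of the 25 testable monocyte and macrophage genes rose and none fell, with a median log2 change of 3.297. ITGAM and ITGAX, integrin chains of myeloid cells, rose 23.6- and 9.83-fold. All 22 lysosomal genes rose (median 1.19), among them the cathepsin genes CTSD (105 ± 3.68 to 761 ± 27.97 CPM) and CTSB (2.29-fold). Of 29 interferon-stimulated genes 25 rose and 1 fell. STAT2, a transcription factor of interferon signaling, rose 2.09-fold, and BST2, an antiviral membrane protein, rose 2.32-fold. Of 30 p53 targets 19 rose and 6 fell, and the cell cycle inhibitor CDKN1A went from 284 ± 9.06 to 948 ± 12.6 CPM, with TP53INP1 and MDM2, the ubiquitin ligase of p53, up 5.58- and 3.13-fold. In camera with a preset correlation of 0.01, adjusted p (Benjamini-Hochberg) was 2.03e-11 for monocyte genes, 3.03e-11 for lysosomal genes, 5.22e-06 for interferon-stimulated genes and 0.00154 for p53 targets.

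All 29 mitosis genes fell at 0.5 µM, with a median of -1.69, and so did all 18 genes of homologous recombination and Fanconi repair (-0.82). CENPF, a kinetochore protein, and TOP2A, topoisomerase II alpha, fell 5.503- and 2.63-fold, BRCA1 1.94-fold, CHEK1, the checkpoint kinase, 2.62-fold and FANCI 2.24-fold. Of 35 replication genes 28 fell and 3 rose, with MCM7 and MCM6, subunits of the replicative helicase, down 2.64- and 2.46-fold and the licensing factor CDT1 down 3.25-fold. Of 25 MYC targets and ribosome biogenesis genes 24 fell and 1 rose. MYC itself went from 637 ± 3.66 to 286 ± 11.98 CPM, ODC1, the first enzyme of polyamine synthesis, fell 3.54-fold and FBL, a nucleolar methyltransferase, 2.17-fold, alongside the lower share of ribosomal protein mRNA. Of 20 ATF4 stress response genes 18 fell and 1 rose, including the amino acid transporter gene SLC7A5 (8.13-fold) and the pseudokinase gene TRIB3 (18.1-fold). Camera adjusted p (Benjamini-Hochberg) was 9.81e-16, 2.3e-06, 1.97e-06, 1.67e-10 and 3.03e-11 for these lists in that order.

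Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, rose in 32 of 35 cases, none falling. Capture on oligo(dT) beads takes only the polyadenylated part, so these counts do not measure total histone mRNA. Of the 35 genes 1 had at least 10 CPM in control, so most changes start from low counts. H2AC6 rose from 22.3 ± 0.7404 to 102 ± 1.82 CPM, H2BC5 5.603-fold and H4C8 3.67-fold. The median was 2.49, or 2.25 with the 6 genes that had no count in a group set to their bounds, and camera adjusted p was 0.000255 (Benjamini-Hochberg). Histone genes, like tubulin, HLA, metallothionein and mitochondrial genes, share sequence with close copies, and how the counting treated shared reads is not given in the sources used here, so values of single members are uncertain. Mitochondrially encoded genes rose in 11 of 13 cases, none falling, in step with their share of counts. MT-CO1, a subunit of cytochrome oxidase, rose 1.602-fold, MT-ND4 1.78-fold and MT-ND5 1.53-fold. Camera adjusted p (Benjamini-Hochberg) was 0.000132 for the mitochondrial list, and adjusted p = 0.194 with an estimated correlation.

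Some lists passed at 0.5 µM only with the preset correlation. Of 10 granulocyte genes 8 rose and 2 fell (camera adjusted p = 0.0424, Benjamini-Hochberg; adjusted p = 0.255 with an estimated correlation), with PRTN3, CSF3R and AZU1 up 3.31-, 2.21- and 1.89-fold. Of 18 stem cell and KMT2A-fusion targets 4 rose and 12 fell (camera adjusted p = 0.0439, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation), with the transcription factor genes MEF2C, BCL11A and MYB down 1.94-, 4.08- and 1.83-fold. Of 13 heat shock genes 1 rose and 9 fell (camera adjusted p = 0.0301, Benjamini-Hochberg; adjusted p = 0.194 with an estimated correlation), HSPH1, HSPD1 and HSPB1 falling 1.84-, 1.57- and 1.36-fold. Of 18 NF-kappaB and inflammatory genes 13 rose and 2 fell, and the chemokine gene CXCL8 went from 2.93 ± 0.991 to 55.6 ± 3.35 CPM, with ICAM1 and IER3 up 2.85- and 2.41-fold. For that list camera gave adjusted p = 0.0482 (Benjamini-Hochberg), and adjusted p = 0.0947 with an estimated correlation. Its call was lost without control replicate 1 (camera adjusted p = 0.05003), control replicate 2 (0.0599), control replicate 3 (0.0610) or cytarabine 0.5 µM replicate 3 (0.0523).

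The other lists did not pass at 0.5 µM, and their members moved in both directions. The apoptosis inhibitor gene BCL2 fell 4.35-fold while BMF, a death-promoting relative, rose 2.14-fold, and 6 of 15 family members rose and 6 fell. IL2RA, the alpha chain of the interleukin-2 receptor, rose from 3.91 ± 0.444 to 60.3 ± 2.64 CPM and SOCS2 fell 1.76-fold, among 4 STAT5 targets that rose and 5 that fell of 11. SAMHD1, which hydrolyzes the active form of cytarabine, rose 3.98-fold and DCK, the kinase that activates it, fell 1.78-fold, among 5 rises and 6 falls of 12 transport and metabolism genes. Tubulins (2 rose and 9 fell of 14; TUBE1 fell 3.92-fold and TUBA1C 1.52-fold), MAPK feedback genes (5 and 9 of 19; ETV5 fell 2.800-fold, PHLDA1 rose 7.02-fold), the unfolded protein response (6 and 6 of 15; XBP1 fell 3.07-fold and EDEM1 1.64-fold), cholesterol synthesis (6 and 10 of 19; STARD4 rose 2.04-fold) and hypoxia genes (7 and 7 of 17; VEGFA fell 8.14-fold, PFKFB3 rose 3.21-fold) had camera adjusted p from 0.0714 to 0.627 (Benjamini-Hochberg). Adjusted over the list alone, counts equalled those over all genes for each list except STAT5 targets, of which 5 rose. Markers of other cell types were few. Of 3 testable T and NK cell genes NKG7 rose to 60.8 ± 2.78 CPM from 19.7 ± 1.82 and CD3D fell to 2.95 ± 1.502 from 11.7 ± 0.151, of 4 megakaryocyte genes 3 rose with no mean above 10 CPM in either group, and of the B cell, erythroid and stromal lists BANK1 and EPOR fell and KRT8 rose, CD79A having 0.4303 ± 0.251 CPM in control and 0.627 ± 0.3002 after cytarabine.

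At 1 µM cytarabine moved most of these lists in the same directions against control. LYZ went from 379 ± 12.4 to 6597 ± 130.0 CPM, CTSD from 105 ± 3.68 to 1282 ± 53.8 CPM, MKI67 from 381 ± 12.03 to 60.7 ± 3.199 CPM and PSAT1 from 590.0 ± 12.2 to 35.4 ± 1.704 CPM. HMOX1, the heme-degrading oxygenase, rose from 0.741 ± 0.338 to 145 ± 6.25 CPM and APOE to 128 ± 2.404 CPM. FLT3 rose 1.37-fold, to 541 ± 7.89 CPM, a log2 fold change of 0.45 ± 0.032. In edgeR's quasi-likelihood test 9375 of 12356 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 4850 rose, 4525 fell and 2955 differed at least 2-fold.

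Genes with no or few control counts were among the largest rises at 1 µM that the naming rule admits. A4GALT, the Gb3 synthase, had no count in any control library and 11.5 ± 1.98 CPM at 1 µM, at least 178-fold higher from a floor of 3 counts over the group. DCANP1 was at least 195-fold higher by the same floor, with 12.6 ± 6.21 CPM. MERTK, a receptor for apoptotic cells, had 3 control counts and was 249.6-fold higher, with a 95% counting interval of 85.0 to 1214. OLR1, a scavenger receptor, reached 23.2 ± 0.6899 CPM from 0.0879 ± 0.0479. The largest falls it admits were in STC2 (345-fold), SLC6A9 (3 counts at 1 µM, 159.6-fold lower, interval 54.3 to 776), INHBE, the phosphatase gene PPM1E, the NKG2D ligand gene ULBP1 (26.01-fold) and PHGDH, which opens serine synthesis (168 ± 5.42 to 6.43 ± 1.33 CPM). Such floors and intervals cover counting error only.

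The 10 lists that passed camera with both correlations at 0.5 µM did so again at 1 µM. Monocyte genes rose in 23 of 25 cases with 1 fall (median 3.09; ITGAM 17.8-fold, ITGAX 8.53-fold), lysosomal genes in 22 of 22 (1.19; CTSB 2.45-fold, HEXA 3.15-fold), interferon-stimulated genes in 27 of 29 with 1 fall (2.28; STAT2 2.51-fold) and p53 targets in 22 of 30 with 4 falls (0.76; CDKN1A 3.73-fold, MDM2 3.84-fold). All 35 testable histone genes rose, with a median of 4.51 or 3.62 with genes without counts at their bounds, H2AC6 reaching 108 ± 6.84 CPM. All 29 mitosis genes (-2.12; CENPF fell 6.63-fold) and all 18 recombination genes (-0.94; CHEK1 fell 3.64-fold) fell, with 30 of 35 replication genes against 2 rises (MCM6 fell 3.14-fold), 24 of 25 MYC targets against 1 (ODC1 fell 4.603-fold, MYC 2.84-fold) and 18 of 20 ATF4 genes against 2 (TRIB3 fell 19.3-fold, SLC7A5 6.69-fold). Camera adjusted p for these 10 lists ran from 3.82e-15 to 7.75e-05 (Benjamini-Hochberg), and each also passed with an estimated correlation.

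Tubulins (3 rose and 9 fell of 14), stem cell and KMT2A-fusion targets (3 and 12 of 18), heat shock genes (1 and 9 of 13) and mitochondrially encoded genes (12 and 0 of 13) passed camera at 1 µM, with adjusted p of 0.0389, 0.0314, 0.0113 and 3.54e-05 (Benjamini-Hochberg). Their calls were lost with adjusted p = 0.15, adjusted p = 0.15, adjusted p = 0.139 and adjusted p = 0.149 with an estimated correlation, and that of tubulins also without cytarabine 1 µM replicate 2 (camera adjusted p = 0.0534). TUBA1B, a main alpha-tubulin gene, fell 1.73-fold, TUBE1 3.72-fold, MEF2C 2.05-fold, BCL11A 4.54-fold, and HSPA8, the constitutive Hsc70 chaperone, 1.36-fold, while MT-ND4 rose 1.97-fold. NF-kappaB genes (12 rose and 3 fell of 18; CXCL8 rose 30.5-fold) stood at a camera adjusted p of 0.0504 (Benjamini-Hochberg), which fell under 0.05 without control replicate 1 (0.0427), control replicate 2 (0.0493), cytarabine 1 µM replicate 1 (0.0477) or cytarabine 1 µM replicate 2 (0.0341). Granulocyte genes (8 and 2 of 10; PRTN3 rose 2.38-fold, CTSG fell 9.95-fold), the BCL2 family (6 and 4 of 15; BCL2 fell 3.48-fold, BMF rose 2.63-fold), STAT5 targets (3 and 4 of 11; IL2RA rose 13.2-fold), MAPK feedback genes (6 and 8 of 19), the unfolded protein response (8 and 6 of 15; CALR rose 1.53-fold, XBP1 fell 4.02-fold), cholesterol synthesis (4 and 12 of 19; FDFT1 fell 1.36-fold), hypoxia genes (8 and 7 of 17) and cytarabine metabolism (4 and 7 of 12; RRM2 fell 1.804-fold, SAMHD1 rose 3.99-fold) did not pass. Adjusted over the list alone, counts differed for the mitochondrial list only, with 13 rises. In the other cell type lists NKG7 rose 2.997-fold to 59.2 ± 2.05 CPM, and the remaining testable members lay below 10 CPM at 1 µM.

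Lists that separated the doses of cytarabine included interferon-stimulated genes and histones, higher at 1 µM, and replication, mitosis and granulocyte genes, lower at 1 µM. HMOX1 was 29.6 ± 0.587 CPM at 0.5 µM and 145 ± 6.25 CPM at 1 µM, PALD1 rose 7.76-fold between the doses, and MFGE8, a bridge to apoptotic cells, 5.01-fold. The IgA receptor gene FCAR fell 2.71-fold, PLXND1 2.39-fold and CTSG, the neutrophil protease cathepsin G, from 49.1 ± 1.01 to 20.9 ± 0.912 CPM. FLT3 fell by 0.12 ± 0.032 on the log2 scale. The edgeR quasi-likelihood test called 2390 genes at a Benjamini-Hochberg adjusted p of 0.05, with 1122 higher at 1 µM, 1268 lower and 175 at least 2-fold apart. List tests, which the plan did not hold for this comparison, were run with both correlations. Those that passed camera with each were interferon-stimulated genes (22 of 29 rose, 0 fell), histones (27 of 35, 0), p53 targets (13 of 30, 1 fell), replication (0 rose, 16 of 35 fell), mitosis (0, 20 of 29), MYC targets (0, 18 of 25), monocyte genes (3, 12 of 25) and granulocyte genes (0, 5 of 10), with adjusted p from 1.03e-18 to 8.05e-05 (Benjamini-Hochberg). Adjusted over the list alone, rises numbered 30 of histones, 15 of p53 targets and 1 of replication genes, and falls 18 of replication, 21 of mitosis, 13 of monocyte and 7 of granulocyte genes. Tubulins, NF-kappaB, STAT5, ATF4, heat shock and lysosome passed with the preset correlation at adjusted p from 0.0279 to 0.0437 (camera, Benjamini-Hochberg) and were lost with an estimated correlation, at adjusted p = 0.113, 0.0754, 0.0709, 0.0709, 0.176 and 0.0541 with an estimated correlation.

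**Figure D2:**
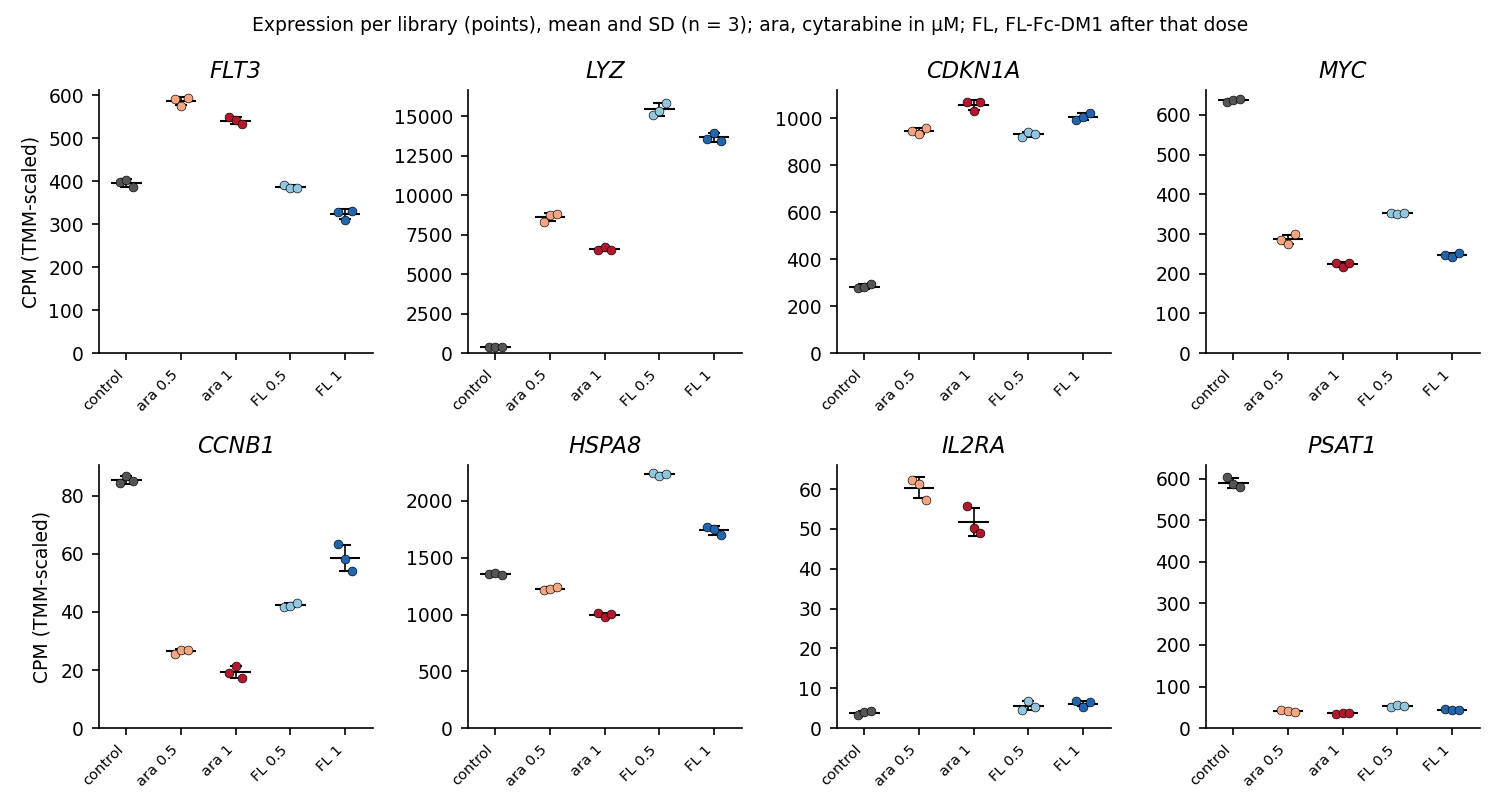
Expression of 8 genes in CPM on linear axes from 0; points are libraries, horizontal bars group means and error bars SD (n = 3), with ara for cytarabine in µM and FL for FL-Fc-DM1 after that dose. FLT3 averaged 395 CPM in control, 587 and 541 after cytarabine and 386 and 323 after FL-Fc-DM1, while PSAT1 stayed far below its control level in every treated library.

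After FL-Fc-DM1 at a pretreatment dose of 0.5 µM, genes of MYC and ribosome biogenesis, chaperones, cholesterol synthesis and mitosis rose against continued cytarabine, while interferon-stimulated genes, p53 targets and STAT5 targets fell. IL2RA fell from 60.3 ± 2.64 to 5.61 ± 1.12 CPM, close to the 3.91 ± 0.444 CPM of control. HSPA8 rose from 1228 ± 14.7 to 2236 ± 12.5 CPM, and LYZ from 8624 ± 273 to 15421 ± 387 CPM. FLT3 fell 1.52-fold, from 587 ± 9.62 to 386 ± 4.96 CPM, a log2 fold change of -0.603 ± 0.032. In edgeR's quasi-likelihood test 5527 of 12356 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 2715 rose, 2812 fell and 392 differed at least 2-fold (84 up and 308 down). In data simulated for this comparison, the test recovered 98 of 100 genes changed by 1 on the log2 scale and 78 of 100 changed by 0.5, and called 7 of 12126 unchanged genes. The unchanged genes include some that failed the filter. Far fewer genes were changed there than were called here, and the spread was edgeR's own estimate, so the simulation does not test the 5527 calls.

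The largest rises that the naming rule admits were in MGAM2, a relative of the intestinal maltase (8.14-fold), FCN1, the monocyte lectin ficolin-1 (5.96 ± 0.512 to 32.01 ± 2.12 CPM), CLEC5A, a myeloid lectin receptor (4.77-fold), the protease inhibitor gene A2M (4.53-fold), the metallothionein gene MT1G (4.53-fold) and the MHC class II gene HLA-DPA1 (3.19-fold). The largest falls it admits after IL2RA were in SPIB, a transcription factor of lymphoid and plasmacytoid cells (4.298-fold), MYBPH (45.1 ± 3.02 to 11.3 ± 0.306 CPM), PPFIA4 (3.98-fold), the costimulatory ligand gene CD80 (3.78-fold) and ABCA1, the cholesterol efflux pump (61.5 ± 2.58 to 17.4 ± 1.29 CPM). Among these 12 genes the highest adjusted p was 1.36e-07, for HLA-DPA1 (edgeR quasi-likelihood test, Benjamini-Hochberg).

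All 25 MYC targets and ribosome biogenesis genes rose at 0.5 µM, by a median of 0.45, with ODC1 up 1.94-fold and the small subunit processome genes RRP12 and UTP20 up 1.85- and 2.18-fold, while the share of counts in ribosomal protein genes was lower than after cytarabine. Of 13 heat shock genes 11 rose and 1 fell (0.46; HSP90AA1 1.69-fold, HSPH1 1.86-fold), and of 15 genes of the unfolded protein response 12 rose and 2 fell (0.52), the endoplasmic chaperones HSPA5, HYOU1 and HSP90B1 rising 1.67-, 1.75- and 1.43-fold. Of 19 cholesterol synthesis genes 16 rose and 1 fell (0.55; SQLE, an epoxidase of the pathway, 1.59-fold). Mitosis genes rose in 19 of 29 cases, none falling (0.25), with CDC20, the activator of the anaphase-promoting complex, up 2.09-fold and cyclin gene CCNB1 up 1.604-fold. Monocyte genes rose in 16 of 25 cases and fell in 6 (0.397; VCAN rose 2.06-fold, S100A9 2.51-fold), and lysosomal genes rose in 12 of 22 with 1 fall (0.16; LAMP1 1.28-fold, CTSD 1.32-fold). Camera adjusted p (Benjamini-Hochberg) for these 7 lists ran from 6.72e-16 to 0.00247, and each passed with an estimated correlation as well.

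Interferon-stimulated genes fell in 20 of 29 cases with no rise (median -0.68), XAF1 from 89.97 ± 3.09 to 44.5 ± 1.88 CPM, the antiviral genes OAS1 and IFIT3 2.61- and 2.52-fold. STAT5 targets fell in 7 of 11 with no rise (-0.52), with PIM1, a serine/threonine kinase, down 1.51-fold and CISH, a feedback inhibitor, down 1.82-fold. Of 30 p53 targets 19 fell and 2 rose (-0.25; TP53INP1 fell 1.89-fold, SESN1 1.37-fold), CDKN1A being 948 ± 12.6 CPM after cytarabine and 932 ± 9.27 after FL-Fc-DM1. Stem cell and KMT2A-fusion targets fell in 11 of 18 with no rise (-0.26; RUNX2 1.39-fold, JMJD1C 1.27-fold). Camera adjusted p (Benjamini-Hochberg) was 8.24e-07, 0.000101, 7.42e-05 and 7.28e-05 for these lists, and each passed with an estimated correlation.

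Lists that did not pass at 0.5 µM held opposing members. RRM2, a ribonucleotide reductase subunit, rose 1.42-fold and the sliding clamp gene PCNA fell 1.12-fold, with 6 rises and 3 falls of 35 replication genes. Recombination genes (1 rose and 8 fell of 18; CHEK1 fell 1.36-fold), histones (4 and 9 of 35; H2AC6 fell 1.72-fold), tubulins (5 and 1 of 14; TUBA1C rose 1.57-fold, TUBB4B 1.56-fold), NF-kappaB genes (5 and 3 of 18; CXCL8 rose 2.17-fold, TNF 2.08-fold), granulocyte genes (3 and 2 of 10; AZU1 fell 1.195-fold), MAPK feedback genes (8 and 2 of 19; FOS rose 1.95-fold), the BCL2 family (2 and 7 of 15; BMF fell 1.96-fold, BCL2L11 1.32-fold), ATF4 genes (6 and 5 of 20; SLC7A5 rose 1.83-fold), hypoxia genes (6 and 6 of 17; LDHA rose 1.73-fold), cytarabine metabolism (5 and 2 of 12; SAMHD1 rose 1.42-fold, NT5C2 fell 1.28-fold) and mitochondrially encoded genes (6 and 2 of 13; MT-ND2 rose 1.14-fold) had camera adjusted p from 0.0669 to 0.806 (Benjamini-Hochberg). Adjusted over the list alone, falls numbered 20 of p53 targets, 14 of stem cell targets, 9 of recombination genes and 1 of mitosis genes, rises 17 of cholesterol genes and 7 each of ATF4 and hypoxia genes, and replication genes had 3 rises and 2 falls. None of the other cell type lists passed. CD3D was 2.95 ± 1.502 and 1.35 ± 0.2502 CPM, a call lost without cytarabine 0.5 µM replicate 2 (adjusted p = 0.127, edgeR quasi-likelihood). NKG7 was 60.8 ± 2.78 and 53.9 ± 3.06 CPM, a call lost without cytarabine 0.5 µM replicate 1 (0.0862) or 2 (0.188) or FL-Fc-DM1 replicate 1 (0.214), 2 (0.0647) or 3 (0.0516). GP1BA was 5.704 ± 0.517 and 3.94 ± 0.5002 CPM, a call lost without cytarabine 0.5 µM replicate 1 (0.0762) or 2 (0.0599) or FL-Fc-DM1 replicate 1 (0.0588) or 2 (0.0942).

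After FL-Fc-DM1 at a pretreatment dose of 1 µM the same groups moved, and replication genes rose with mitosis genes. CCNB1, the mitotic cyclin, rose from 19.2 ± 2.07 to 58.6 ± 4.55 CPM against 85.5 ± 1.31 in control, and RRM2 from 58.7 ± 4.92 to 98.4 ± 2.81 CPM. IL2RA fell from 51.6 ± 3.53 to 6.15 ± 0.713 CPM and ABCA1 from 72.4 ± 5.28 to 18.6 ± 3.37 CPM. FLT3 fell 1.67-fold, from 541 ± 7.89 to 323 ± 11.7 CPM, a log2 fold change of -0.74 ± 0.033. In edgeR's quasi-likelihood test 5646 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 2906 rose, 2740 fell and 515 differed at least 2-fold. Replicates of the 1 µM groups spread more than those of the others. At summed counts of 5 to 20 the variance between pairs was 2.65 to 3.13 times that of counting in these groups and 1.32 to 1.66 times in the other groups.

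FCN1 rose 8.13-fold, FPR3, a formyl peptide receptor, 7.001-fold, CLEC5A 6.33-fold, MGAM2 5.22-fold, CDC20 from 6.69 ± 0.0724 to 32.2 ± 3.13 CPM and the cytokine gene IL1B 4.23-fold, the largest rises under the naming rule. The largest falls under it after IL2RA were in OTOF (6.18-fold), GGT5, a glutathione-cleaving enzyme (13.03 ± 0.825 to 2.15 ± 0.731 CPM), ABCA1, PPFIA4 and SPIB (3.56-fold). The highest adjusted p of these 12 genes was 5.39e-08, for IL1B (edgeR quasi-likelihood test, Benjamini-Hochberg).

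All 29 mitosis genes rose at 1 µM, by a median of 0.88, with the kinase PLK1 up 2.73-fold, and 21 of 35 replication genes rose with 1 fall (0.29; GINS4 1.62-fold). Histone genes rose in 19 of 35 cases and fell in 6 (1.02), H1-5 2.83-fold, H3C11 3.78-fold and H4C3 2.599-fold. MYC targets rose in 21 of 25 (0.36; ODC1 1.97-fold, NCL 1.39-fold) and heat shock genes in 10 of 13 (0.42; HSP90AA1 1.82-fold), with none falling in either list. The unfolded protein response (12 rose and 2 fell of 15, 0.46; CALR 1.53-fold, HSPA5 1.52-fold), cholesterol synthesis (16 and 1 of 19, 0.67; IDI1 1.91-fold), monocyte genes (15 and 6 of 25, 0.25; LYZ 2.07-fold) and lysosomal genes (13 and 2 of 22, 0.12; CTSD 1.396-fold) also passed upward. Interferon-stimulated genes fell in 24 of 29 (-0.65; MX1 2.61-fold, IFIT3 2.81-fold) and STAT5 targets in 6 of 11 (-0.53; PIM1 1.78-fold), with no rise in either. Of p53 targets 17 of 30 fell and 1 rose (-0.23; CCNG1 fell 1.399-fold, DDB2 1.44-fold), and of stem cell targets 11 of 18 fell and 2 rose (-0.34; RUNX2 fell 1.499-fold, JMJD1C 1.45-fold). Camera adjusted p (Benjamini-Hochberg) for these 13 lists ran from 1.36e-20 to 0.0131, and each passed with an estimated correlation.

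Tubulin genes rose in 7 of 14 cases and fell in 2 at 1 µM, with TUBA1B going from 341 ± 7.01 to 522 ± 8.38 CPM, TUBA1C up 1.85-fold and TUBB 1.32-fold. The tubulin list passed camera at adjusted p = 0.0155 (Benjamini-Hochberg), a call lost at adjusted p = 0.0879 with an estimated correlation. Recombination genes rose in 10 of 18 with no fall (BLM, a helicase, 1.42-fold, FANCI 1.32-fold) and had a camera adjusted p of 0.0593 (Benjamini-Hochberg), or 0.0445 without cytarabine 1 µM replicate 2. MAPK feedback genes (6 rose and 1 fell of 19; ETV5 rose 1.54-fold, DUSP4 2.18-fold) had 0.0847 in the same test, or 0.0406 without cytarabine 1 µM replicate 1. NF-kappaB genes (5 and 7 of 18; CXCL8 rose 1.62-fold, TNFAIP3 fell 1.56-fold), granulocyte genes (3 and 2 of 10; FPR1 rose 2.94-fold), the BCL2 family (2 and 5 of 15; BMF fell 1.46-fold), ATF4 genes (7 and 5 of 20; SLC7A5 rose 1.63-fold, DDIT4 fell 1.704-fold), hypoxia genes (6 and 6 of 17; LDHA rose 1.74-fold), cytarabine metabolism (5 and 2 of 12) and mitochondrially encoded genes (4 and 2 of 13; MT-CO1 fell 1.18-fold) did not pass. Adjusted over the list alone, rises numbered 24 of replication genes, 21 of histones, 8 each of tubulins and ATF4 genes and 5 of MAPK feedback genes, and falls 19 of p53 targets and 7 each of histones and hypoxia genes. The other cell type lists did not pass either, and calls for CD3D, NKG7, TUBB1 and GP1BA were lost in 1 or more of the refits that left out a library of the FL-Fc-DM1 or cytarabine group, with adjusted p from 0.0578 to 0.208 (edgeR quasi-likelihood). CD3D was 4.17 ± 1.26 and 2.58 ± 0.2702 CPM (lost without cytarabine 1 µM replicate 1, 0.114, or 2, 0.208, or FL-Fc-DM1 replicate 1, 0.109, 2, 0.0604, or 3, 0.105), NKG7 59.2 ± 2.05 and 53.1 ± 1.58 (cytarabine replicate 1, 0.118, or 3, 0.1103, or FL-Fc-DM1 replicate 1, 0.0994, 2, 0.158, or 3, 0.0578), TUBB1 0.622 ± 0.404 and 1.74 ± 0.5698 (cytarabine replicate 2, 0.0803, or 3, 0.0669, or FL-Fc-DM1 replicate 2, 0.0731) and GP1BA 7.95 ± 0.0922 and 5.702 ± 0.618 (FL-Fc-DM1 replicate 2, 0.0893).

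**Figure D3:**
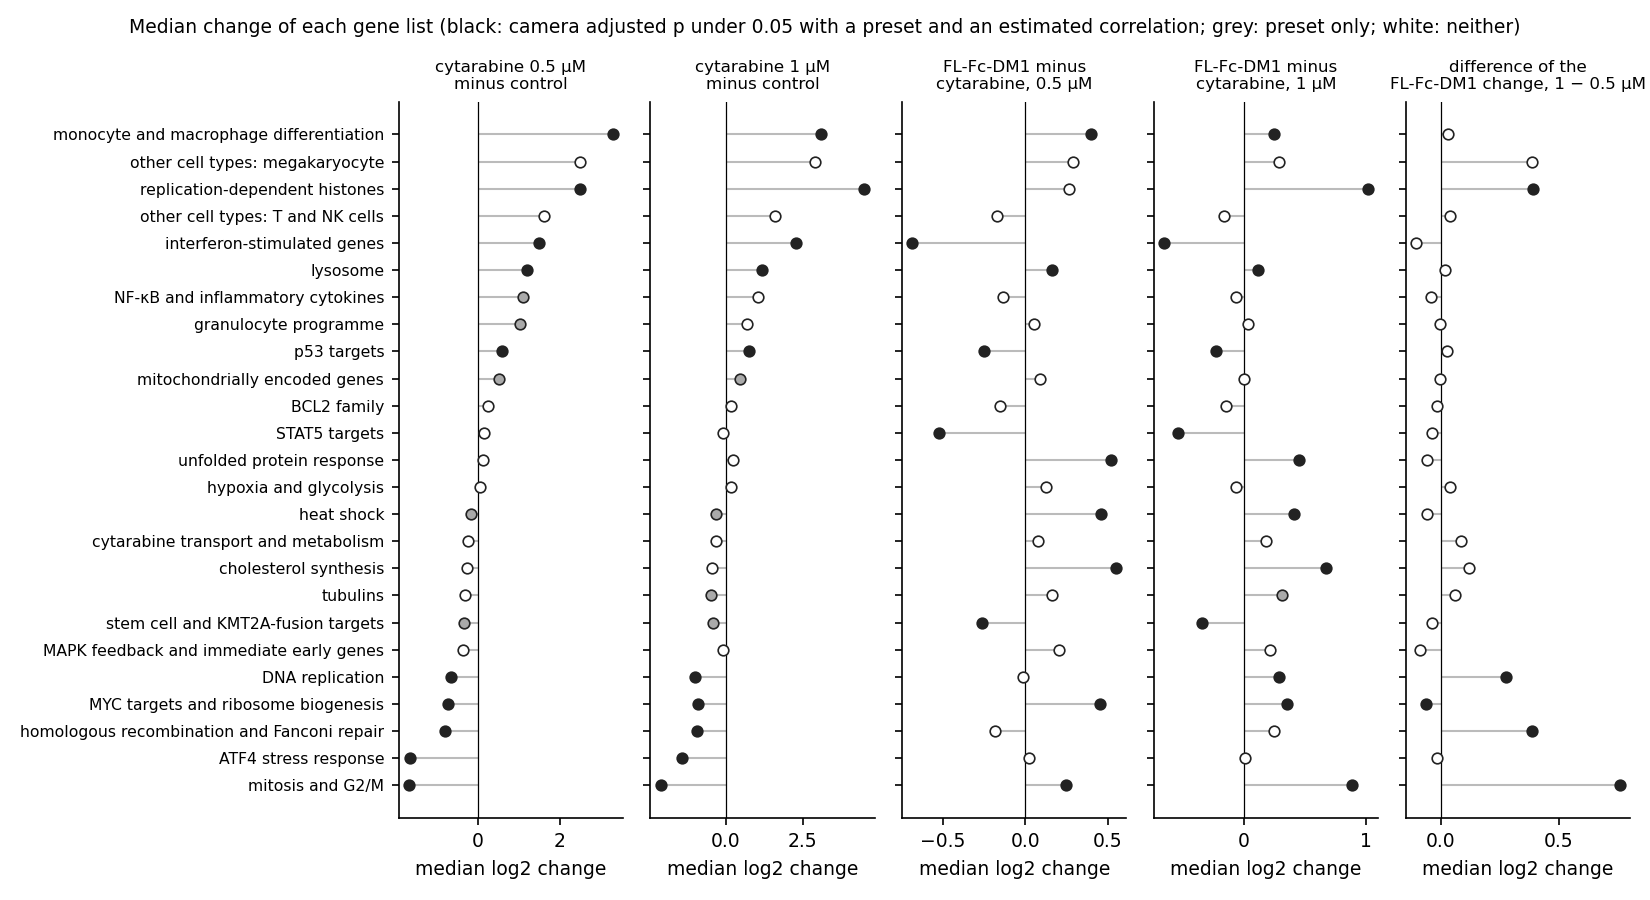
Median log2 change of each gene list in 5 comparisons, each panel on its own horizontal scale; black points passed camera (Benjamini-Hochberg adjusted p under 0.05) with a preset and an estimated correlation, grey points with the preset alone and white points with neither. Mitosis genes lay at -1.69 and -2.12 after cytarabine against control, and at 0.25 and 0.88 after FL-Fc-DM1 against cytarabine.

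The change after FL-Fc-DM1 differed between the pretreatment doses in genes that included 23 of the 29 mitosis genes. NEK2, a centrosome kinase, rose by 1.57 ± 0.14 at 1 µM and had 0.25 ± 0.14 at 0.5 µM, a difference of 1.33 ± 0.20. For CDC20 the changes were 2.27 ± 0.11 and 1.06 ± 0.10, and for CCNB1 1.61 ± 0.073 and 0.68 ± 0.072. The secretogranin gene SCG2 differed by -0.95 ± 0.15 in the other direction, GGT5 by -1.19 ± 0.25, PDXP, a pyridoxal phosphatase, by -1.105 ± 0.30, and FPR3 by 1.295 ± 0.34. The difference for FLT3 was -0.14 ± 0.046 with an adjusted p of 0.101 (edgeR quasi-likelihood, Benjamini-Hochberg), and 0.0358 with DESeq2. The test of the difference called 379 genes, 264 with the higher change at 1 µM and 115 with the lower, 17 of them at least 2-fold apart (edgeR quasi-likelihood, Benjamini-Hochberg). The FPR3 call was lost without cytarabine 0.5 µM replicate 1 (adjusted p = 0.192, edgeR quasi-likelihood) or 2 (0.0655), cytarabine 1 µM replicate 1 (0.0807) or 3 (0.0792), FL-Fc-DM1 after 0.5 µM replicate 1 (0.0720), 2 (0.0636) or 3 (0.0904), or FL-Fc-DM1 after 1 µM replicate 2 (0.0727). The PDXP call was lost without any cytarabine 0.5 µM replicate (0.0579, 0.0903 and 0.0888), cytarabine 1 µM replicate 2 (0.0792) or 3 (0.0931), FL-Fc-DM1 after 0.5 µM replicate 1 (0.111) or FL-Fc-DM1 after 1 µM replicate 2 (0.0884).

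The plan did not hold list tests of the difference, and these were added. Mitosis genes were higher in 23 of 29 cases in that test, with none lower (29 higher when adjusted over the list alone), and the median difference was 0.76. Replication genes (7 of 35, 20 over the list alone, median 0.28), recombination genes (7 of 18, 9 over the list alone, 0.39) and histones (1 of 35 either way, 0.39) also passed with the higher change at 1 µM, with none lower, and MYC targets were slightly lower (1 of 25, 2 over the list alone, -0.064). Camera adjusted p (Benjamini-Hochberg) was 6.13e-41, 1.49e-13, 2.57e-07, 0.00261 and 0.00415, and all 5 passed with an estimated correlation. Tubulins (3 higher of 14, 4 over the list alone; 0.0596) passed camera without cytarabine 0.5 µM replicate 2 (0.0380), cytarabine 1 µM replicate 1 (0.0383), or, of the FL-Fc-DM1 libraries, replicate 1 after 0.5 µM (0.0201), replicate 2 after 0.5 µM (0.0360) or replicate 2 after 1 µM (0.0165). Mitochondrially encoded genes (1 lower of 13, 2 over the list alone; 0.194) passed without cytarabine 0.5 µM replicate 3 (0.0174) or FL-Fc-DM1 after 0.5 µM replicate 1 (0.0201). No other list passed, with adjusted p of 0.163 and above. These groups include the 1 µM libraries, whose replicates spread more.

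Averaged over both doses, FL-Fc-DM1 against cytarabine raised FCN1 by 2.72 ± 0.081, MGAM2 by 2.705 ± 0.13 and CLEC5A by 2.46 ± 0.10 on the log2 scale, and IL2RA (-3.25 ± 0.076), OTOF (-2.74 ± 0.16) and GGT5 (-2.01 ± 0.12) had the largest falls that the naming rule admits. FLT3 fell, with a log2 fold change of -0.67 ± 0.023 over 6 libraries against 6. In this average 7086 genes were called by edgeR's quasi-likelihood test (Benjamini-Hochberg), 3512 up and 3574 down, 472 at least 2-fold. List tests were added here too. Camera passed 9 lists upward and 4 downward, and 12 of these 13 passed with an estimated correlation, tubulins (8 rose and 2 fell of 14) being lost at adjusted p = 0.119 with an estimated correlation.

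Against control, the cells given FL-Fc-DM1 after cytarabine kept high monocyte and lysosomal genes and low ATF4, replication and mitosis genes. S100A9 was 112 ± 6.600 CPM after FL-Fc-DM1 at the 0.5 µM pretreatment dose against 0.5101 ± 0.103 in control. PSAT1 was 53.3 ± 2.08 CPM at the 0.5 µM and 44.7 ± 1.92 CPM at the 1 µM pretreatment dose against 590.0 ± 12.2. FCN1 had 3 control counts and was 505-fold higher at 0.5 µM (counting interval 172 to 2454) and 690.2-fold at 1 µM (236 to 3351). FPR1 had 2 control counts and was 241-fold higher at 0.5 µM (66.3 to 1998), and at 1 µM FPR3 and A4GALT, with no control count, were at least 249- and 186-fold higher. STC2 was 0.733 ± 0.211 and 0.515 ± 0.525 CPM, the vasoactive peptide gene ADM2 0.229 ± 0.199 CPM at 0.5 µM, INHBE 0.175 ± 0.304 CPM at 1 µM, and SLC6A9 had 2 counts in each FL-Fc-DM1 group, 221-fold (61.0 to 1833) and 193-fold (53.3 to 1600) lower than control. FLT3 was 386 ± 4.96 CPM at 0.5 µM against 395 ± 8.51 in control, a log2 fold change of -0.033 ± 0.032 and an adjusted p of 0.37, and 323 ± 11.7 CPM at 1 µM, a log2 fold change of -0.29 ± 0.033 and an adjusted p of 1.27e-08 (edgeR quasi-likelihood, Benjamini-Hochberg). That test called 8550 genes at 0.5 µM (4325 up, 4225 down, 2307 at least 2-fold) and 8798 at 1 µM (4420 up, 4378 down, 2446 at least 2-fold).

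Monocyte genes were higher than in control in 25 of 25 cases at 0.5 µM and 24 of 25 at 1 µM, and mitosis genes lower in 29 and 28 of 29, with medians of -1.48 and -1.03. Histone medians were 3.24 and 5.74, or 2.31 and 4.83 with genes without counts at their bounds. ATF4 genes were lower in 18 of 20 at each dose (-1.73 and -1.54), stem cell targets in 13 and 15 of 18 (16 at 1 µM when adjusted over the list alone), and MYC targets in 16 and 24 of 25, against 4 and 0 higher. Cholesterol synthesis genes were higher in 13 of 19 at each dose, with 0 and 2 lower. In list tests that the plan did not hold, camera passed 17 lists at 0.5 µM and 14 at 1 µM, and 12 at each dose held with an estimated correlation. At 0.5 µM the calls lost were p53 targets (adjusted p = 0.0594 with an estimated correlation), granulocyte genes (0.204), STAT5 targets (0.0774), the unfolded protein response (0.0626) and mitochondrially encoded genes (0.0774), and at 1 µM NF-kappaB genes (0.0552) and mitochondrially encoded genes (0.0847).

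Genes moved by cytarabine tended to move the other way after FL-Fc-DM1. Genes are not independent replicates. The cytarabine 0.5 µM change and the FL-Fc-DM1 change after 1 µM pretreatment share no library. Across 12356 genes they had a Pearson r of -0.226 and a Spearman rho of -0.326. Of 4577 genes called in both, 72.1% had opposite signs, with 1615 rising then falling and 1685 falling then rising, against 1042 and 1023 for independent lists. Cytarabine 1 µM and FL-Fc-DM1 after 0.5 µM pretreatment also share no library. For this pair r was -0.226 (rho -0.348) and 73.1% of 4625 genes called in both had opposite signs. Pairs at matched dose share the cytarabine libraries with opposite sign, which alone gave a simulated r of -0.504 at 0.5 µM and -0.488 at 1 µM. Their observed r was -0.269 and -0.290, and the observed covariance of -0.158 and -0.202 stood against a simulated -0.0222 and -0.0218.

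Cytarabine changes at the 0.5 and 1 µM doses had an r of 0.951 across genes (rho 0.952). These comparisons share the control libraries, and unchanged groups simulated against them gave 0.484, with a covariance of 0.0209 against the observed 1.38. Both doses raised 4270 genes and lowered 3994, against 1844 and 1593 for independent lists, and part of that excess may come from the shared controls, which 3 libraries are too few to split. FL-Fc-DM1 changes at the 2 pretreatment doses share no library and had an r of 0.607 and a rho of 0.731. At both doses 2066 genes were raised and 1952 lowered, against 639 and 624 for independent lists. With genes averaging at least 10 CPM that r was 0.836. The relations in this family numbered 6, no p-value was computed for any of them, and all were computed over the same 12356 genes.

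**Figure D4:**
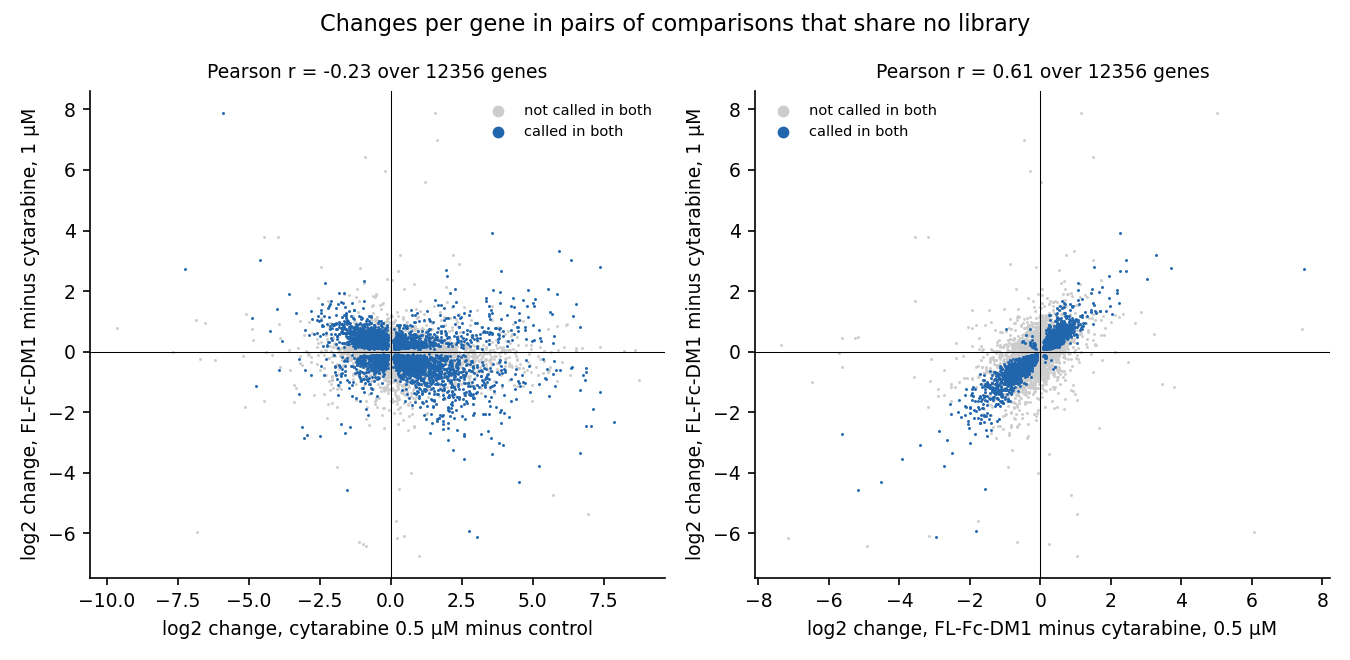
Log2 fold change per gene in 2 pairs of comparisons that share no library; each point is 1 of 12356 genes, blue where edgeR's quasi-likelihood test called it in both. The cytarabine 0.5 µM change and the FL-Fc-DM1 change after 1 µM pretreatment (left) had r = -0.23. The FL-Fc-DM1 changes at the 2 pretreatment doses (right) had r = 0.61.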

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

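The test of a difference between doses was planned for genes and added for gene lists once the data were in hand, and the tests of explanations in this part were all chosen after the results were seen. The change from the cytarabine to the FL-Fc-DM1 groups differed between the pretreatment doses for 379 genes in edgeR's quasi-likelihood test. That change also holds the withdrawal of cytarabine, so the difference cannot be assigned to FL-Fc-DM1 alone. In the fit of only these groups, 262 genes were called, and 10 of 100 splits of the same 12 libraries, drawn from the 200 possible within doses with the real one included, called as many, so chance is not excluded by this count. The highest other split called 6818 genes, many times the real count. It exchanged the treatments of all 3 libraries at 1 µM, so it tested the common FL-Fc-DM1 change and not the difference. The 9 other splits as large all moved unequal numbers of libraries between treatments in each dose. That carries the common FL-Fc-DM1 change into the difference. Among the 49 splits that moved equal numbers the highest other count was 0 against 262. Apart from the real one, these mix both treatments within each group, which adds the treatment difference to the spread and lowers the count. Splits of these libraries thus cannot decide on chance for the difference.

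Mitosis genes rose more after FL-Fc-DM1 at the 1 µM than at the 0.5 µM pretreatment dose. The median difference was 0.76 on the log2 scale, with 23 of 29 called. In the list test of the difference, replication genes (median 0.28, 7 of 35 called), recombination and Fanconi genes (0.39, 7 of 18) and histones (0.39, 1 of 35) also passed with the higher change at 1 µM, and MYC targets passed slightly lower (-0.064). A wider spread of the 1 µM replicates as the whole source is argued against by a fit with a spread for each group. In that fit 22 of the 29 mitosis genes were called with the higher change at 1 µM. Cells held in mitosis by a tubulin-binding drug cannot be judged by the replication list, which rose at 1 µM with a median of 0.29. Cells pass through replication before they reach mitosis, so renewed cycling followed by arrest would raise both lists. Cells that cycle again once cytarabine is withdrawn may explain the rise itself. The p53 targets fell at both doses (medians -0.25 and -0.23), with 0 of 30 called in the difference, while replication and recombination genes had the higher change at 1 µM. Whether renewed cycling is the source of the dose difference thus stays open. Part of the difference lies in a lower start at 1 µM. Mitosis genes had a median of -2.12 against control after cytarabine at 1 µM and -1.69 at 0.5 µM. CCNB1 was 26.4 and 19.2 CPM after cytarabine at 0.5 and 1 µM, and 42.3 and 58.6 CPM after FL-Fc-DM1 at these pretreatment doses. Withdrawal and FL-Fc-DM1 coincide in every library, so they cannot be told apart.

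Replicates of both 1 µM groups spread more than those of the other groups. At summed counts of 5 to 20 the lowest variance between 1 µM pairs was 2.65 times that of counting, above the highest of the other pairs, 1.66, and the 1 µM libraries held fewer genes with exactly 1 count, 441 ± 31.1 and 422 ± 65.1 against 765 ± 21.9, 729 ± 16.3 and 735 ± 28.9 (SD, n = 3). Fewer distinct molecules behind each count, for example from more PCR duplicates, is a candidate explanation that predicts such excess at low counts. Variation between cultures as the whole source is argued against, since the excess at summed counts of 2000 or more was only 2.12 times that at 5 to 20, where it would have to grow with the count. Lower depth is argued against for the cytarabine groups, whose total counts at 1 µM were 1.03 times those at 0.5 µM. For the FL-Fc-DM1 groups this ratio was 0.8597, and it is argued against there by the 0.5 µM libraries thinned to the lowest 1 µM total, whose highest pair stood at 1.48 against 2.79 for the lowest pair at 1 µM. No other biological explanation was tested.

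Single genes whose FL-Fc-DM1 change differed between the doses, by the test of the difference in log2 units, were CDC20 (1.20), CCNB1 (0.93), PLK1 (0.83), CHEK1 (0.71), BLM (0.55), FANCI (0.55), GINS4 (0.55) and MKI67 (0.40), with the higher change at 1 µM. FPR3 (1.295), BMF (0.42), LYZ (0.21) and the tubulin genes TUBA1B (0.44) and TUBB (0.27) were also higher there. GGT5 (-1.19), TNF (-0.76), VCAN (-0.56), FOS (-0.43), CXCL8 (-0.42), PIM1 (-0.23) and MT-CO1 (-0.12) were lower at 1 µM. The GGT5 call was lost with a spread for each group (limma voom adjusted p = 0.108). Of 98 genes named in the comparisons of FL-Fc-DM1 with cytarabine, these 20 differed between the doses. Over all genes tested, 379 of 12356 (3.07%) did. The 98 were chosen by size of change or p in the comparisons that make up the difference, so their share is raised by selection.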

How the results depend on the processing

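Counts of called genes stayed within 1.5 times the main count for all 9 comparisons under every alternative except the log2 threshold of 1, which by its construction left 2646 and 2955 genes for cytarabine at 0.5 and 1 µM, 392 and 515 for FL-Fc-DM1 against cytarabine, 175 between the cytarabine doses, 17 for the difference between doses, 2307 and 2446 for FL-Fc-DM1 against control and 472 for the mean over doses. Among alternatives fixed before the data were seen the difference between doses moved most, from 379 genes to 559 without the low-count filter, 262 with only these groups and 253 to 494 in the refits without a library. FL-Fc-DM1 against cytarabine at the 1 µM pretreatment dose went from 5646 genes to 4353 with only its groups. It went to 4335 with a spread for each group, a fit chosen after seeing the data. Of those, 4343 and 4324 were among the 5646. No gene called in the main test and in any alternative changed sign. The r between the FL-Fc-DM1 changes rose from 0.607 to 0.836 with genes of at least 10 CPM, a setting that leaves out low counts. The share of rises among calls moved by under 10 percentage points with other scalings, which moved the median gene by -0.02 to 0.01 on the log2 scale.

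The replicate number used as a block gave 9072, 9415, 5596, 5700, 2422, 438, 8591, 8811 and 7138 genes for the 9 comparisons in the order of the methods, cytarabine first, and turned 1 list call, tubulins in the difference between doses (camera adjusted p = 0.0326, Benjamini-Hochberg). Deviations of libraries with the same number correlated at -0.0623 to 0.0799, so the numbers do not pair the samples.

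Of 125 list results, 25 in each of 5 comparisons (cytarabine against control and FL-Fc-DM1 against cytarabine at each dose, and the difference between doses), 10 lost their call with an estimated correlation and 1 gained one with DESeq2 size factors, and of the refits without a library 5 lost a call, 13 gained one and 882 stayed on the same side of the threshold. Fry, which does not compare a list with other genes, gained 38 calls and reversed 3 signs. Its signed -log10 p was -3.88 and -1.56 for the BCL2 family after cytarabine at 0.5 and 1 µM and 1.34 for cytarabine metabolism at 0.5 µM, and the cause was not tested. Of 350 results for genes selected by the naming rule, 2 lost a call with DESeq2, 2 without the filter, 1 with DESeq2 size factors, 4 with only the groups compared and 6 with a spread for each group, and 39 refits without a library lost one while 2145 did not. These were CD3D, NKG7, GP1BA and TUBB1 after FL-Fc-DM1 and FPR3, GGT5 and PDXP in the difference between doses, genes of low level or of changes near the threshold. FLT3 in the difference between doses was the only call gained, with DESeq2 (adjusted p = 0.0358). Depth limits genes under about 1 CPM, such as most histone genes in control.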

Other observations

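The gene groups in this part were chosen after seeing the data, and so were all tests of hypotheses. All 9 testable MHC class II genes, which present antigen to helper T cells, rose after cytarabine at both doses, with HLA-DRA going from 10.3 ± 1.54 CPM in control to 236 ± 1.29 and 165 ± 6.100 CPM and the invariant chain gene CD74 from 157 ± 4.33 to 783 ± 3.197 and 694 ± 10.1 CPM. After FL-Fc-DM1 they rose further, 7 of 9 at 0.5 µM (median 0.58) and 9 of 9 at 1 µM (median 1.23), HLA-DRA reaching 386 ± 1.84 and 396 ± 13.97 CPM, and 3 of 9 rose more at 1 µM in the test of the difference. The 5 metallothionein genes, which bind zinc and copper, went the other way with cytarabine, all falling at both doses, and all 5 rose after FL-Fc-DM1 (medians 1.20 and 0.96), MT2A from 3.82 ± 0.453 to 10.4 ± 0.459 CPM at 0.5 µM. Reads of HLA and metallothionein genes can be shared between close copies, so single members are uncertain.

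The ferritin genes and HMOX1 were higher than in control at both doses of cytarabine. FTH1, the ferritin heavy chain, was 555 ± 6.78 CPM in control, 2288 ± 36.7 and 4004 ± 64.7 CPM after cytarabine at 0.5 and 1 µM, and 2707 ± 25.4 and 4766 ± 182 CPM after FL-Fc-DM1. FTL, the light chain, was 1231 ± 43.6 CPM in control and 4904 ± 57.1 and 5170.4 ± 55.9 CPM after cytarabine, doses that did not differ at the threshold (adjusted p = 0.09003, edgeR quasi-likelihood, Benjamini-Hochberg), and 5827 ± 203 and 6341 ± 304 CPM after FL-Fc-DM1. HMOX1 was 29.6 ± 0.587 and 145 ± 6.25 CPM after cytarabine and 51.02 ± 1.65 and 197 ± 7.804 CPM after FL-Fc-DM1, and NQO1, another gene of the antioxidant response, was 19.3 ± 0.708 CPM in control, 15.4 ± 1.79 and 23.4 ± 1.93 CPM after cytarabine and 18.7 ± 3.72 and 41.3 ± 4.59 CPM after FL-Fc-DM1. The glucose-sensing arrestin genes TXNIP and ARRDC4 fell after FL-Fc-DM1, TXNIP from 1654 ± 30.5 to 767 ± 22.6 CPM at 0.5 µM (log2 fold change -1.11 ± 0.034) and from 1219.7 ± 41.9 to 465 ± 21.4 CPM at 1 µM (-1.39 ± 0.034), and ARRDC4 by -1.33 ± 0.046 and -1.53 ± 0.051, to levels below control in both cases.

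The further rise of MHC class II genes after FL-Fc-DM1 might come from more mRNA of CIITA, their master activator. CIITA had a log2 change of -0.49 ± 0.055 at 0.5 µM, a fall, and -0.069 ± 0.054 at 1 µM (adjusted p = 0.309, edgeR quasi-likelihood, Benjamini-Hochberg). Both lay below the class II medians by more than 2 SE, which argues against a further rise of CIITA mRNA as the source at both doses. Its level stayed above control, at 72.8 ± 5.25 and 95.2 ± 3.62 CPM after FL-Fc-DM1 against 15.6 ± 0.862 CPM. After cytarabine it was 102 ± 5.57 and 99.9 ± 1.28 CPM, and a delayed effect of that earlier rise was not tested. The FL-Fc-DM1 change of CIITA differed between doses by 0.42 ± 0.077 (adjusted p = 0.00157, edgeR quasi-likelihood, Benjamini-Hochberg), CIITA having fallen at 0.5 µM. CIITA protein was not measured. Lower activity of the liver X receptor (LXR) could join the rise of cholesterol synthesis genes with the fall of its target ABCA1. Without ABCA1, the other 11 testable LXR targets gave a camera p of 0.721 at 1 µM and 0.146 at 0.5 µM, with 4 rising and 3 falling at 1 µM and 1 rising and 6 falling at 0.5 µM. With ABCA1 the list passed downward at 0.5 µM (camera adjusted p = 0.0338, Benjamini-Hochberg) and not at 1 µM (0.273), so this stays open.

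Because a label names THP-1 for the FL-Fc-DM1 groups, another cell line in those libraries was tested as an explanation of the FL-Fc-DM1 changes. Lines of different origin differ in genes that are on in the first and off in the other. Genes at 10 CPM or more in every library of a group and 1 CPM or less in every library of the other numbered 0 between FL-Fc-DM1 and cytarabine at each dose, against 34 and 36 between cytarabine and control, which argues against another cell line.

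Splits of the same libraries were counted for the other comparisons too. For FL-Fc-DM1 against cytarabine over both doses, 100 splits were drawn from 200 within doses. Only 1, the real one, called as many as 6818 genes, and the highest other called 1531. By this rank alone, chance assignment of these libraries to treatments is an unlikely source of that count. The size of the gap adds little. Splits that mix both treatments within a group add the treatment difference to the spread, which lowers their counts. Chance between cultures is not covered, since the libraries of a group may not be separate cultures. For comparisons of 3 libraries against 3 the 10 splits are too few for a share under 0.05. In each of these 7, the real split alone (1 of 10) reached its count, and the highest other was 0. The other splits mix the groups compared, which adds their difference to the spread, so the 0 gives little support. The real counts in fits of only the groups compared were 9493 and 9343 for cytarabine at 0.5 and 1 µM, 6416 and 4353 for FL-Fc-DM1 against cytarabine, 2338 between the cytarabine doses, and 9078 and 8325 for FL-Fc-DM1 against control.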
